A study of Mus musculus with 5 samples.

How the data were processed

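Chromatin occupancy of RNA polymerase II (RNAPII), of the NELF-A and NELF-B subunits of the negative elongation factor, and of R-loops was profiled in primary mammary epithelial cells of virgin mice aged 6 to 8 weeks and of mixed strain. Per the labels' protocols, the thoracic and inguinal glands were digested to organoids and then to single cells. Chromatin was sonicated for ChIP-seq. For DRIP-seq, in which an antibody against RNA-DNA hybrids pulls down R-loops, genomic DNA was digested instead. Libraries were amplified with 15 PCR cycles for RNAPII (1 ng of DNA) and for DRIP, and with 18 cycles for NELF-A and NELF-B (0.2 ng of DNA). The NELF antibodies were made in house.

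The series holds 5 samples, and 4 of them had a peak list that was analysed. The fifth, DRIP-seq after RNase H treatment, which degrades the RNA of R-loops, was not analysed here, so no peak could be checked for sensitivity to RNase H. The titles of the RNAPII and DRIP samples name 2 libraries each, and 1 list was deposited for both together. How the libraries were combined, the peak caller, its threshold and any input control are not given in the sources used here. Per the submitters' processing notes, reads were aligned with BWA to mm9.

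The deposited lists give chromosome, first base, last base and 1 whole number per peak, with 2 further columns that are constant in every row. That whole number is called the score here. The authors' score has no stated unit; it rises with peak width (Spearman's rho across peaks 0.977 for RNAPII, 0.878 for NELF-A, 0.870 for NELF-B and 0.938 for DRIP). The lowest score per 250 bp was 51.8 in the RNAPII list, 4.12 for NELF-A, 3.25 for NELF-B and 18.8 for DRIP, so each list had a floor on score per base. The score was used to rank peaks within 1 list and was never compared between lists. Peaks start and end on a 250 bp grid in 1-based coordinates, except 1 DRIP peak on the X chromosome. Adjacent peaks without a gap occur in each list (312 in RNAPII, 176 in NELF-A, 48 in NELF-B and 499 in DRIP). They were kept as deposited except where joining is stated. Sequencing depth is unknown from these files.

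A peak was counted as shared when it overlapped a peak of the other list by 1 bp or more. Shares carry 95% Wilson binomial intervals, which cover counting error alone. Each share was set beside 1000 random placements of the first list on the 250 bp grid of the same chromosome, between the first and last base that any of the 4 lists covers. A second set of 1000 placements moved each peak 10 to 100 kb up or down, which keeps regional crowding. With 1 list per target there is no spread between replicates, peaks are not replicates, and no p-values were computed. DRIP overlap of RNAPII peaks with and without NELF was compared as an odds ratio with a 95% interval (Woolf). This was done over all RNAPII peaks and within 3 classes of RNAPII peak width and of score. The classes of score were of roughly equal size, and those of width held 2929, 2732 and 2057 peaks. Pooled odds ratios at equal width, score per base or distance are Mantel-Haenszel estimates. Width was matched exactly and score per base by 3 classes. Distance to the nearest RNAPII peak was matched by class only: under 1 kb, 1 to 3 kb, 3 to 10 kb and over 10 kb. Ratios of median scores carry percentile intervals from 1000 bootstrap draws over peaks. For the analysis of wide RNAPII domains, touching peaks were joined within each list and their scores summed. RNAPII domains of 5 kb or more were kept. A domain was oriented by its highest-score NELF-A peak where the centre of that peak lay in the outer 25% at either end.

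The comparisons of overlap and score and those within classes of width and score were fixed before the data were examined, as were their alternatives, except that touching peaks were merged for the odds ratios after. The local shifts, the set of regions of extra-high signal and the analysis of wide domains were chosen after. For the domains, the 5 kb minimum, the 20% end zones and the orientation by the outer 25% were settled after looking at DRIP in domains of several widths. The regions of extra-high signal hold, in at least 3 lists, a peak of the top 1% by score per base or of the 10 highest scores. A first definition by score per base alone missed a block on chromosome 11 that leads several lists, and the scores were added to it after a first run. The regions named were also chosen by a rule fixed beforehand: the 5 highest-score and 3 widest peaks per list, and the 10 regions shared by all 4 lists with the best sum of ranks by score. Another rule would have named genes, and shares of peaks at gene starts and gene lists for luminal and basal cells, other cell types, immediate early and heat shock responses, pausing, DNA repair, hormone response and housekeeping were planned. They were not run: the gene table in use is of GRCm38, the peaks are in mm9, the lists name no genes, and coordinates were not converted between builds. Peaks are therefore given by mm9 position, and whether they lie in exons, introns or promoters was not determined. The GRCm38 table served to count protein-coding genes per chromosome (21631 on the 20 chromosomes with peaks).

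Overlaps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the counts of all 12 ordered pairs equalled those of bedtools 2.31.1. The functions were tested on simulated data. For NELF-A peaks simulated to share 40% with RNAPII, 40.4% was recovered where 40.5% was expected with chance overlap added. In 20 pairs of unrelated simulated lists of those sizes the fold over random placement lay between 0.801 and 1.23. With DRIP simulated at an odds ratio of 2 at equal RNAPII width, the pooled estimate averaged 1.99 and the unadjusted one 3.58. In the 419 domains, DRIP simulated without a side gave more DRIP on the NELF side of the midpoint in 50.4% of domains with a difference, and DRIP simulated on that side alone gave 99.98%.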

Results

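RNAPII, the NELF-A and NELF-B subunits of the negative elongation factor, and R-loops were mapped in primary mouse mammary epithelial cells to show how they are distributed over the genome. NELF is a complex that holds RNAPII in a paused state soon after transcription starts. NELF-B, also called COBRA1, is known as a binding partner of the tumour suppressor BRCA1. R-loops are hybrids of nascent RNA with its DNA template that leave the other DNA strand single. Each target had 1 peak list and no replicate lists, so intervals cover counting error alone. Positions are in mm9, scores are the authors' own value per peak, and the sequencing depth is unknown.

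RNAPII formed both short peaks and long domains, NELF formed compact peaks, and DRIP-seq, the assay for R-loops, gave mostly short peaks. The RNAPII list held 7718 peaks with a median width of 1000 bp, covering 13.4 Mb. Of these, 379 peaks (4.91%) were wider than 5 kb, and they made up 30.4% of the covered length. NELF-A had 10782 peaks with a median width of 1000 bp, of which 6 exceeded 5 kb. NELF-B had 3925 peaks with a median width of 750 bp, of which 5 exceeded 5 kb. DRIP had 10031 peaks with a median width of 750 bp, and 146 of them (1.46%) exceeded 5 kb. All 20 chromosomes with peaks, the autosomes and the X chromosome, were represented in each list.

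NELF and RNAPII occupied the same sites to a large extent, and nearly every NELF-B peak lay on a NELF-A peak. Of the NELF-B peaks, 92.5% (3631 of 3925, 95% interval 91.6 to 93.3%) overlapped NELF-A and 77.8% (76.5 to 79.1%) overlapped RNAPII. Of the NELF-A peaks, 54.1% (53.2 to 55.1%) overlapped RNAPII and 32.9% (32.0 to 33.8%) overlapped NELF-B. Seen from the polymerase, 72.3% of RNAPII peaks (71.3 to 73.3%) overlapped NELF-A and 38.2% (37.2 to 39.3%) overlapped NELF-B. Randomly placed RNAPII peaks overlapped NELF-A at 1.09% and NELF-B at 0.369% on average, and local shifts gave 3.57% and 1.33%. None of the 1000 local shifts reached more than 4.26% and 1.72%, so the observed shares were 20.3-fold and 28.7-fold above the local means.

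RNAPII peaks with NELF scored higher than those without. The median score was 300 for RNAPII peaks that overlapped NELF-A and 183 for the others, a ratio of 1.64 (95% bootstrap interval 1.40 to 1.75). It was 391 with NELF-B and 216 without, a ratio of 1.81 (1.75 to 1.88). Peaks with NELF were also wider, and divided by width the ratios were 1.18 and 1.26. The 4944 NELF-A peaks outside RNAPII peaks had a median score of 15, against 37 for those on RNAPII, and a median width of 750 bp against 1000 bp. The lowest score in the NELF-A list was 9. NELF-A peaks that lay on none of the other 3 targets numbered 4254, or 39.5% of that list.

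**Figure D1:**
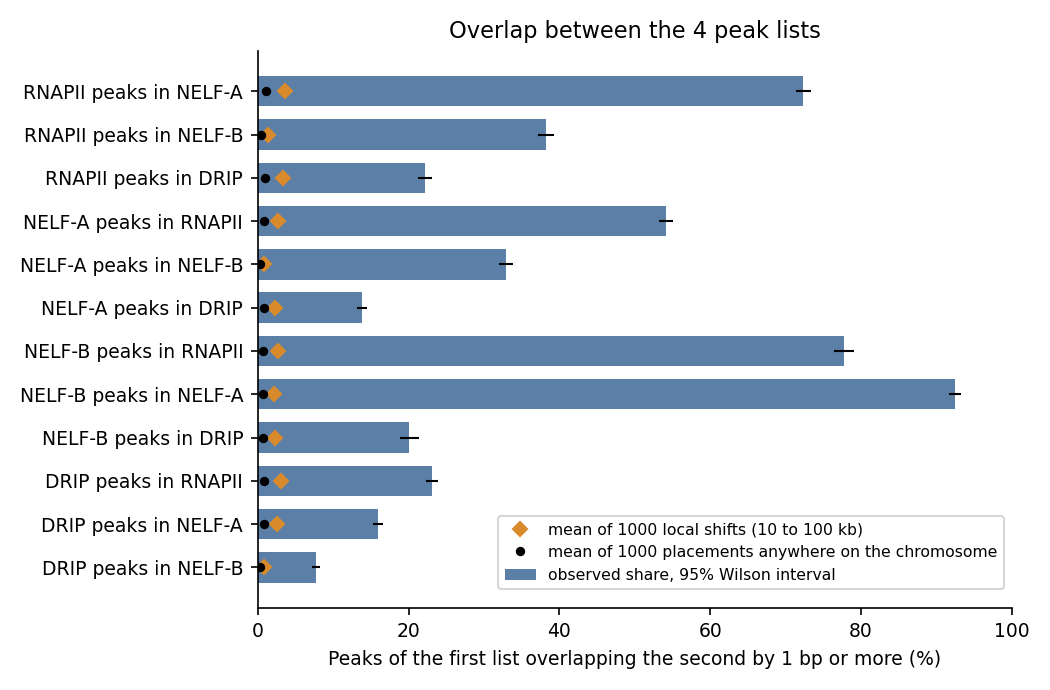
Share of peaks of the first list that overlapped the second (horizontal axis, percent) for the 12 ordered pairs of lists. Bars are observed shares with 95% Wilson intervals, black circles the mean of 1000 placements anywhere on the same chromosome and orange diamonds the mean of 1000 local shifts of 10 to 100 kb. NELF-B in NELF-A is the longest bar at 92.5%, and DRIP in NELF-B the shortest at 7.68%.

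R-loop signal overlapped RNAPII and NELF at a minority of sites, yet far above random placement. Of the DRIP peaks, 23.1% (2315 of 10031, interval 22.3 to 23.9%) overlapped RNAPII, 15.9% (15.2 to 16.7%) overlapped NELF-A and 7.68% (7.17 to 8.21%) overlapped NELF-B. Local shifts of the DRIP peaks gave 3.02%, 2.53% and 0.878%, so the observed shares were 7.65-fold, 6.31-fold and 8.74-fold higher. In the reverse direction, 22.2% of RNAPII peaks (21.3 to 23.1%), 13.9% of NELF-A peaks (13.2 to 14.5%) and 20.1% of NELF-B peaks (18.8 to 21.3%) overlapped DRIP. RNAPII peaks with DRIP had a median score of 605.5 against 226 for the others, a ratio of 2.68 (2.54 to 2.85) that was 1.29 after division by width. All 6 shares depended on peak width: with every peak set to 500 bp around its centre, 5.83%, 5.71% and 3.54% of DRIP peaks overlapped RNAPII, NELF-A and NELF-B, and 7.54%, 5.32% and 9.07% of RNAPII, NELF-A and NELF-B peaks overlapped DRIP. Counting peaks within 1000 bp as shared raised the DRIP peaks with NELF-A to 25.03% and with NELF-B to 13.9%.

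The larger part of the DRIP list lay apart from the other targets. Of the DRIP peaks, 7469 (74.5%, interval 73.6 to 75.3%) overlapped none of RNAPII, NELF-A and NELF-B. Their median width was 500 bp and their median score 45, near the lowest score in the DRIP list, 38. The 696 DRIP peaks that overlapped all 3 had a median width of 1750 bp and a median score of 178. Within 10 kb of an RNAPII peak lay 44.6% of DRIP peaks, and 28.5% lay more than 100 kb from any RNAPII peak. Whether either kind of DRIP peak was lost after RNase H was not analysed here.

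The data also allow the question whether R-loop signal accompanies NELF at sites of RNAPII. Over all RNAPII peaks, DRIP overlapped 23.7% (1324 of 5583) of those with NELF-A and 18.2% (388 of 2135) of those without, an odds ratio of 1.40 (1.23 to 1.59). For NELF-B the shares were 29.8% and 17.5%, an odds ratio of 2.01 (1.80 to 2.24). Peaks with both subunits numbered 879 with DRIP and 2059 without it. With NELF-A alone they numbered 445 and 2200, with NELF-B alone 1 and 12, and with neither 387 and 1735. Over all peaks, the higher DRIP share was thus seen with both subunits and not with NELF-A alone. Whether this holds within classes of width was not tested. Peaks counted as without NELF-B include those with NELF-A alone. The relation to NELF-A, taken as listed, differed between 3 classes of RNAPII peak width, of 2929, 2732 and 2057 peaks. In the narrow class, of 500 to 750 bp, DRIP was found at 5.72% of peaks with NELF-A and 10.6% of peaks without, an odds ratio of 0.512 (0.389 to 0.674). In the middle class, of 1000 to 1500 bp, the shares were 17.1% and 17.6% and the odds ratio was 0.968 (0.752 to 1.25), an interval that includes no difference. In the wide class, of 1750 bp and more, DRIP was found at 54.9% of peaks with NELF-A and 34.4% without, an odds ratio of 2.32 (1.89 to 2.85).

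For NELF-B the odds ratio was 0.797 (0.563 to 1.13) in the narrow class, 1.11 (0.911 to 1.36) in the middle class and 2.13 (1.79 to 2.54) in the wide class. Without the regions of extra-high signal described further on, that of the narrow class was 0.649 (0.445 to 0.946). This left out 9 of 2929 narrow peaks, so the lower value rests on few peaks. The narrow class was compared at equal distance, as given below, for NELF-A only. Classes of RNAPII score gave the same order for NELF-A, with 0.475 (0.352 to 0.640) in the lowest, 0.718 (0.556 to 0.926) in the middle and 1.68 (1.38 to 2.06) in the highest class. Score rises closely with width (Spearman's rho 0.977), so these classes are no separate check. Setting all peaks to 500 bp around their centres ended the excess in the wide class, where the odds ratio became 1.01 (0.783 to 1.30) for NELF-A and 1.09 (0.822 to 1.45) for NELF-B. Over all peaks it turned the odds ratio for NELF-A to 0.574 (0.485 to 0.680) and ended the excess for NELF-B, at 0.868 (0.719 to 1.05). That setting keeps only the centre of a wide peak, so it changed which peaks counted as overlapping. Over all RNAPII peaks, overlap with NELF-A fell from 72.3% to 60.9% and with DRIP from 22.2% to 7.54%. It therefore cannot show whether width produced the excess. Between wide peaks of exactly equal listed width the pooled odds ratio for NELF-A was 2.505 (2.007 to 3.127). Narrow RNAPII peaks without NELF-A more often lay near other RNAPII peaks: 26.6% of them had no other RNAPII peak within 10 kb, against 81.3% of narrow peaks with NELF-A. At equal distance class to the nearest RNAPII peak the odds ratio of the narrow class was 1.22 (0.865 to 1.73). Among isolated narrow peaks it was 0.887 (0.490 to 1.60), and both intervals include no difference. In the wide class the odds ratio at equal distance class was 3.82 (2.99 to 4.87).

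**Figure D2:**
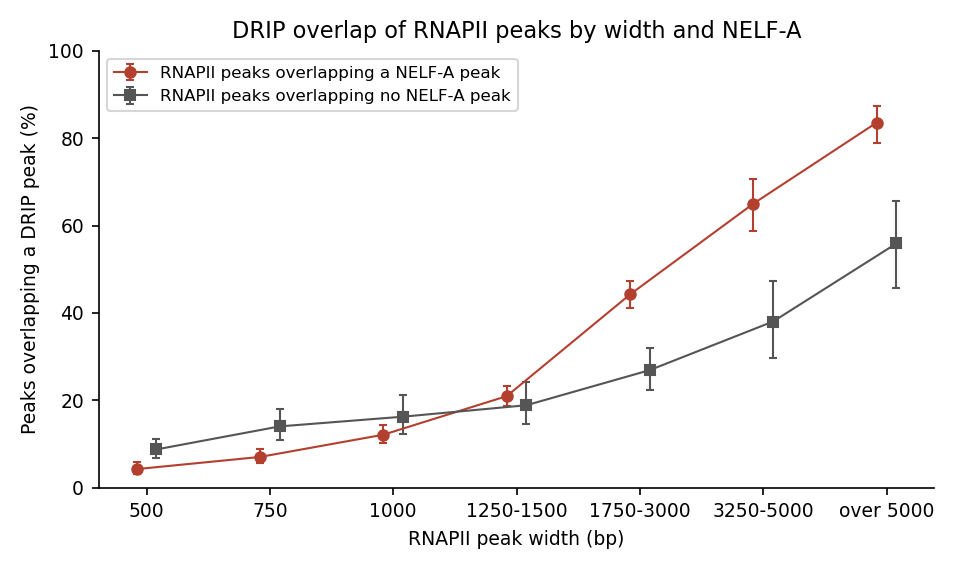
Share of RNAPII peaks that overlapped a DRIP peak (vertical axis, percent) by RNAPII peak width (horizontal axis, classes in bp), for peaks with NELF-A (red circles) and without (grey squares), with 95% Wilson intervals. Peaks of 500 bp overlapped DRIP at 4.28% with NELF-A and 8.79% without, and peaks over 5000 bp at 83.6% with and 55.9% without.

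Within long RNAPII domains, NELF lay close to an end and DRIP spread over the inside. Touching peaks were joined within each list, which gave 419 RNAPII domains of 5 kb or more. NELF-A was present in 325 of them (77.6%), NELF-B in 251 (59.9%) and DRIP in 321 (76.6%). Of the NELF-A peaks centred in these domains, 72.0% (319 of 443, interval 67.7 to 76.0%) lay within the outer 20% at either end, where an even spread would put 40%. For NELF-B this was 79.0% (73.9 to 83.3%). For DRIP it was 40.1% (36.4 to 43.9%), a share that pools both ends and cannot show the difference between them described next. NELF-A occupied the outer 20% at 1 end of 264 domains and at both ends of 21.

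DRIP was unevenly spread between both sides of the domains. In 293 domains the highest-score NELF-A peak lay in the outer 25% at 1 end and gave the domain an orientation. DRIP covered on average 45.9% of the NELF-A side, up to the midpoint, and 24.7% of the far side. DRIP covered more of the NELF-A side in 190 domains and more of the far side in 43, or 81.5% (76.1 to 86.0%) of those with a difference; the other 60 showed none. Coverage was 41.0% of domains at the NELF-A end, highest at 52.2% in step 4 of 20 equal steps, and 13.3% at the far end. With NELF-B in place of NELF-A, 80.9% (74.8 to 85.8%) of domains with a difference had more DRIP on the NELF side. Of all NELF-B peaks, 92.5% overlapped NELF-A, so this is no separate check.

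**Figure D3:**
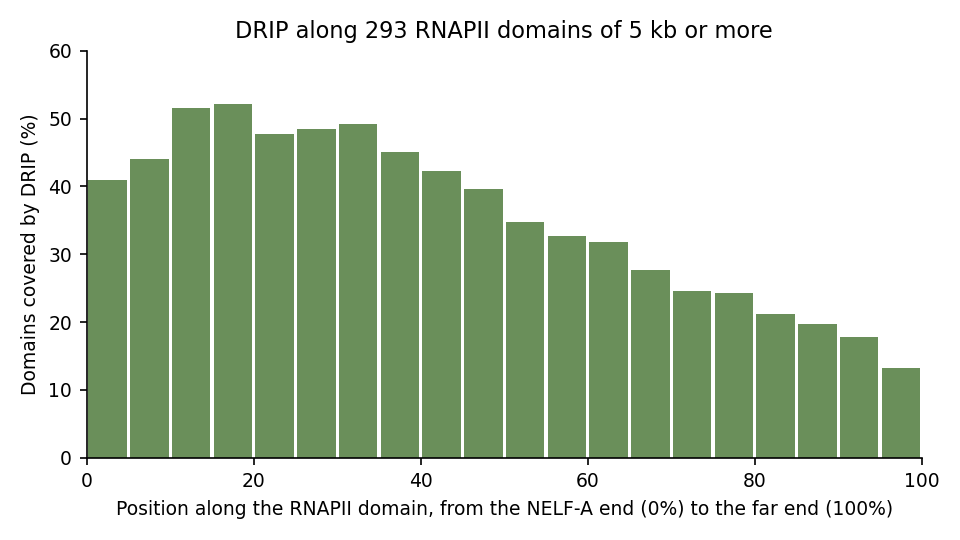
DRIP along 293 RNAPII domains of 5 kb or more, each scaled to its length and turned so that its highest-score NELF-A peak lies at the left. Bars give the percentage of domains covered by a DRIP peak (vertical axis) in 20 equal steps from the NELF-A end (horizontal axis, percent of the domain); they fall from 52.2% in step 4 to 13.3% at the far end.

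The highest-score RNAPII peaks were long domains that also held NELF-A, NELF-B and DRIP. The first was a 36500 bp domain on chromosome 19 from 5814251 to 5850750 with a score of 42660. The next were on chromosome 12 from 40922751 to 40950750 with 32619, on chromosome 1 from 192985501 to 193011000 with 31277, on chromosome 8 from 86720751 to 86755250 with 31142, and on chromosome 7 from 19867751 to 19896250 with 27742. The widest RNAPII peak, of 51750 bp, lay on chromosome 11 from 49607251 to 49659000; it held NELF-A and DRIP and no NELF-B peak. The second widest, of 43500 bp on chromosome 10 from 117240251 to 117283750, overlapped all 3 other targets. Since RNAPII score rises with width (Spearman's rho 0.977), a ranking by score picks long peaks by itself. As a class, RNAPII peaks over 5 kb with NELF-A overlapped DRIP at 83.6%.

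In contrast, the 5 highest-score peaks of NELF-A and of NELF-B all lay in 3 regions, on chromosomes 17, 11 and 2, which DRIP and RNAPII peaks also overlapped. These belong to 16 regions of extra-high signal, in which at least 3 lists have a peak of the top 1% by score per base or of the 10 highest scores; reads of repeated sequence were not ruled out there. A peak on chromosome 17 from 39979751 to 39986000 ranked first for NELF-A with a score of 3128 and first for NELF-B with 1092. The same region, up to 39986250, ranked 4 for DRIP with 8366 and was in the RNAPII list with 8185. On chromosome 11, between 3030501 and 3100250, lay a single DRIP peak of 69750 bp with the highest DRIP score, 25407. Within it were the NELF-A peaks of ranks 2 and 3 by score, from 3049251 to 3074250 with 1201 and from 3080501 to 3097250 with 790. The second NELF-B peak, from 3052251 to 3075000 with 953, and that of rank 4, with 848, lay there too. On chromosome 2, from 98506251 to 98507750, NELF-A had its score of rank 4, 759, and NELF-B its score of rank 3, 856, in peaks with identical ends.

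Of the 5 highest-score DRIP peaks, 2 overlapped no other target, on the X chromosome from 166577501 to 166633000 with a score of 11510 and on chromosome 6 from 47687001 to 47717000 with 4944. The second DRIP peak by score, 22429, covered chromosome 9 from 2999751 to 3038750 and overlapped all 3 other targets. It is also a region of extra-high signal. The rule for such regions needs at least 3 lists, so it could not flag the 2 peaks that overlapped no other target. Reads of repeated sequence were not ruled out at those 2 peaks either.

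Joining the peaks of all lists gave 19136 regions, of which 955 held all 4 targets, 2534 held 3, 2935 held 2 and 12712 held 1. Besides the regions on chromosomes 17, 11 and 19 described above, the 10 regions with the best sum of ranks included 7 others. A region on chromosome 8 from 10980751 to 11015000 ranked 27 for RNAPII, 29 for NELF-A, 46 for NELF-B and 20 for DRIP. One on chromosome 11 from 69208501 to 69227250 ranked 43, 30, 38 and 24 in the same order, and one on chromosome 1 from 36364251 to 36385250 ranked 56, 32, 59 and 8. The remaining 4 were on chromosome 5 from 125860251 to 125875250, chromosome 4 from 94711751 to 94720750, chromosome 8 from 87496751 to 87505750 and chromosome 12 from 56582251 to 56595250. Of the 10 regions, those on chromosomes 17 and 5 and the one near 3 Mb on chromosome 11 are regions of extra-high signal.

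**Figure D4:**
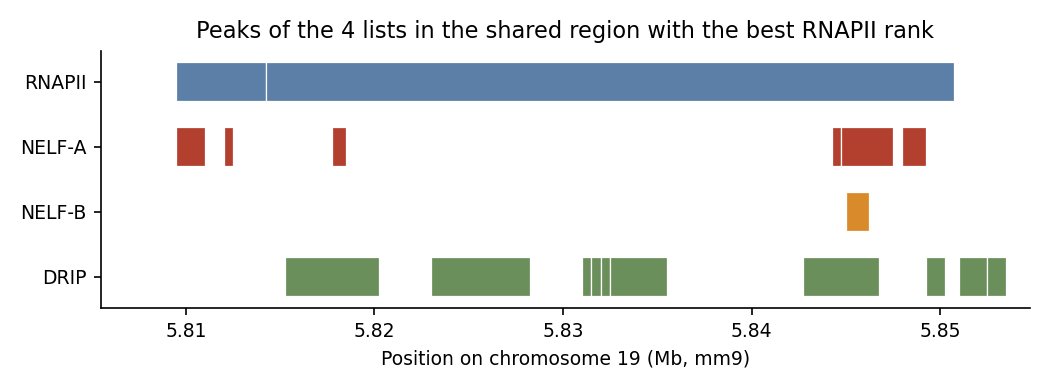
Peaks of the 4 lists on chromosome 19 around the highest-score RNAPII peak (horizontal axis, position in Mb, mm9); each box is 1 peak, drawn to scale. The NELF-A peak of highest score in the region, 188, spans 5844751 to 5847500 towards the right end of the RNAPII domain and overlaps the NELF-B peak from 5845001 to 5846250, while DRIP peaks lie along the domain.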

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

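Every overlap stayed above random placement with all 3 kinds of placement, which were run on the peaks as listed alone, and the shares moved beyond their counting intervals with the definition of a peak and of sharing. The local shift and the removal of regions of extra-high signal were chosen after the data were seen, as were all settings for wide domains and the odds ratios with touching peaks merged. Each group had 1 list, so no replicate could be left out. Leaving out the X chromosome and shifting peaks in a circle moved no result beyond its interval, nor did orienting domains by NELF-B or by their outer 10%. The same held for leaving out regions of extra-high signal, with an exception. Without these regions the odds ratio for NELF-B in the narrow class, 0.6487 (0.4446 to 0.9464), no longer included no difference. That change rests on few peaks, since 9 of 2929 narrow peaks were left out, and its cause was not tested. Unmoved results numbered 17 with 50% of the shorter peak, 5 within 1000 bp, 6 among the upper 50% by score, 2 at 500 bp and 22 with touching peaks merged. Requiring 50% of the shorter peak lowered the overlap with DRIP to 19.9% of RNAPII, 11.95% of NELF-A and 18.24% of NELF-B peaks, and the share of DRIP peaks on RNAPII, NELF-A and NELF-B to 20.1%, 12.54% and 6.629%. Allowing 1000 bp between peaks raised RNAPII on NELF-A, NELF-B and DRIP to 74.24%, 39.82% and 29.67%, NELF-A on RNAPII, NELF-B and DRIP to 55.61%, 34.71% and 19.59%, NELF-B on RNAPII, NELF-A and DRIP to 79.16%, 93.83% and 29.45%, and DRIP on RNAPII, NELF-A and NELF-B to 30.38%, 25.03% and 13.89%. The odds ratios of DRIP then were 1.207 (NELF-A, all), 0.6901 (NELF-A, narrow class) and 1.598 (NELF-B, all). Among the upper 50% of each list by score, RNAPII overlapped NELF-A at 70.29% and DRIP at 30.36%, NELF-A overlapped RNAPII, NELF-B and DRIP at 49.65%, 36.72% and 16.89%, NELF-B overlapped RNAPII, NELF-A and DRIP at 69.04%, 93.61% and 24.3%, and DRIP overlapped RNAPII, NELF-A and NELF-B at 31.01%, 20.89% and 10.52%; the odds ratio for NELF-B over all peaks was 1.698. The narrow class held too few of these peaks for an odds ratio.

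With all peaks set to 500 bp, RNAPII overlapped NELF-A, NELF-B and DRIP at 60.9%, 30.37% and 7.541%, NELF-A overlapped RNAPII, NELF-B and DRIP at 43.66%, 31.52% and 5.324%, NELF-B overlapped RNAPII, NELF-A and DRIP at 59.97%, 86.98% and 9.07%, and DRIP overlapped RNAPII, NELF-A and NELF-B at 5.832%, 5.712% and 3.539%. The odds ratio of DRIP over all RNAPII peaks reversed to 0.574 (0.4845 to 0.68) for NELF-A and fell to 0.8677 (0.7186 to 1.048), which includes no difference, for NELF-B. For NELF-A and NELF-B it was 0.7436 and 0.8497 in the middle class and 1.008 and 1.093 in the wide class; this setting trims wider peaks and extends narrower ones, and the cause was not tested. Merging touching peaks raised RNAPII on NELF-A to 74.56% and on NELF-B to 39.67%. The fold over placements was lower with local shifts: 20.28, 28.73 and 6.52 for RNAPII on NELF-A, NELF-B and DRIP, 20.25, 40.97 and 5.917 for NELF-A on RNAPII, NELF-B and DRIP, 29.2, 42.71 and 8.887 for NELF-B on RNAPII, NELF-A and DRIP, and 7.647, 6.307 and 8.74 for DRIP on RNAPII, NELF-A and NELF-B. Scores divided by width gave ratios of 1.184, 1.264 and 1.294 for RNAPII peaks with NELF-A, NELF-B and DRIP. In domains of 10 kb or more, 77.5% of NELF-A peaks lay near an end, and with bases within 1 kb of NELF left out 72.02% of the 168 domains with a difference had more DRIP on the NELF-A side. Peaks at gene starts, the fixed gene lists, positions within promoters and the use of summits were not run.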

Other observations

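Tests at equal width, at equal score per base, among isolated narrow peaks and, for wide peaks, at equal distance were set out before their results were seen; those without regions of extra-high signal (redefined after a first run), of narrow peaks at equal distance and of domain sides were chosen after. For isolated narrow peaks, the rule that leaves the question open when an interval holds both no difference and the starting value was also added after; by the rule set out first, that result met what broken-up domains predict. The rule that leaving out under 5% of the peaks or domains decides nothing was added after as well.

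The chromosomes differed in their DRIP peaks more than in their RNAPII peaks. Among the autosomes, DRIP peaks ranged from 25.1 per 100 protein-coding genes on chromosome 13 to 74.4 on chromosome 11, with 69.2 on chromosome 15 and 61.5 on chromosome 5. RNAPII peaks ranged from 25.3 per 100 genes on chromosome 7 to 49.5 on chromosome 18. Chromosome 11 held 7.44% of the genes, 9.46% of RNAPII peaks, 9.02% of NELF-A peaks and 11.9% of DRIP peaks. Of the DRIP peaks that overlapped no other target, 12.1% lay on chromosome 11 and 1.93% on chromosome 13, which held 3.83% of the genes. The X chromosome held 4.47% of the genes, 1.88% of RNAPII peaks, 2.24% of NELF-A peaks, 1.55% of NELF-B peaks and 1.69% of DRIP peaks.

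Wide RNAPII peaks with NELF-A overlapped DRIP more often than wide peaks without it (odds ratio 2.32). Between peaks of exactly equal listed width the pooled odds ratio was 2.505 (2.007 to 3.127). With every peak set to 500 bp around its centre, however, the excess was lost (1.008, 0.7834 to 1.298). That setting also changed which peaks counted as overlapping NELF-A or DRIP: RNAPII on NELF-A fell over all peaks from 72.34% to 60.9%. Why the excess was lost was not tested. Equal width and class of score per base together left 2.187 (1.681 to 2.845). Equal distance class to the nearest RNAPII peak gave 3.818 (2.991 to 4.873). A candidate explanation is that wide RNAPII peaks with NELF-A hold the start of a transcribed unit, where R-loops may form, while wide peaks without it are other parts of such units; this needs gene positions and was not tested. Reads of repeated sequence stay open, since leaving out regions of extra-high signal (2.3, 1.871 to 2.828) took away 19 of 2057 peaks, as do base composition and the cutting sites of the DNA digestion, since no mm9 sequence was used.

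Narrow RNAPII peaks showed the opposite, an odds ratio of 0.512, which joining touching peaks left at 0.5238 (0.3878 to 0.7074). Narrow peaks within 10 kb of another RNAPII peak overlapped DRIP at 12.5% (10.7 to 14.5%), isolated ones at 4.37% (3.52 to 5.43%), and most narrow peaks without NELF-A were of the first kind. The deficit of DRIP at narrow peaks with NELF-A was no longer seen at equal distance class to the nearest RNAPII peak. There the pooled odds ratio was 1.222 (0.8649 to 1.726). Among isolated narrow peaks alone it was 0.8868 (0.4904 to 1.604), an interval that holds both no difference and the starting value, so whether narrow peaks without NELF-A are pieces of wide domains broken up by gaps remains open. Leaving out regions of extra-high signal (0.4768, 0.3599 to 0.6318) took away 9 of 2929 peaks and leaves open whether reads of repeated sequence play a part.

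The lean of DRIP to the NELF-A side of long RNAPII domains was also seen over bases more than 1 kb from NELF. With every base within 1 kb of a NELF-A or NELF-B peak left out, 72.02% (64.8 to 78.26%) of domains with a difference still had more DRIP on that side. DRIP peaks that overlap NELF were not left out, and their bases beyond 1 kb still counted. Coincidence of both signals at the same sites therefore stays open. Without domains in regions of extra-high signal the share was 81.66% (76.14 to 86.14%), but this took away 4 of the 233 domains with a difference, so reads of repeated sequence stay open. An untested hypothesis is that NELF marks the start of these domains and that hybrids are more frequent over the first part of the transcript, which could be tested against gene positions in mm9. A fall in RNAPII density towards the far end was not tested, as the lists give 1 score per peak.

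The regions of extra-high signal numbered 16 and covered 197 kb. They held 41 RNAPII, 42 NELF-A, 40 NELF-B and 29 DRIP peaks, and 3 of the regions met the rule in all 4 lists.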
